A study of Homo sapiens with 4 samples.

How the data were processed

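Guide DNA was measured in 4 libraries from BJ cells, a line of human skin fibroblasts, that carried a tamoxifen-inducible oncogenic HRAS and dCas9, the cleavage-dead Cas9 used for CRISPR interference. Per the labels, 2 independent clones, a and b, were each sampled before treatment (D0, the control) and 21 days after 4-hydroxytamoxifen was given at 100 nM (D21). Transduced cells had been selected with puromycin at 2 µg/mL. Per the labels' protocols, the guide cassettes were amplified from genomic DNA in 2 rounds of PCR, the first with 40 pooled reactions of 6.6 µg DNA and 18 cycles per library. The libraries hold PCR reads without molecular identifiers, so intervals on shares cover counting error only.

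The deposited values are a normalised read count per guide, used here as a signal on a linear scale. The submitters' processing notes name bcl2fastq, MAGeCK and GRCh38, with the role and version of each not given in the sources used here. In the deposited table every column had a lowest value of 1, and the values minus 1 summed to 20000000 in each library. Values minus 1 were whole multiples of a fixed step per library, within 0.01 of a whole number for 100% of the values in 3 libraries and 99.999% in D21 of clone b. By those steps the libraries held about 22749968 and 22902359 reads at D0 and 19781210 and 19144452 at D21 in clones a and b. The median negative control guide had 314 and 317 reads at D0 and 99 and 67 at D21, so ratios at D21 are the less precise side. The planned count model was not run, since the deposited values were normalised and carried the added 1, although reads could be recovered by these steps.

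The table had 69695 rows, 1285 of them non-targeting control guides and 68410 targeting guides assigned to 6634 elements. A total of 2478 rows repeated a guide with the same strand, position and values, and each of the 67217 distinct guides entered the ranking once. Of these, 926 belonged to more than 1 element and counted in each. Most elements (6544) had 10 distinct guides and the largest had 26. The element identifiers matched 0 symbols, and 0 of 1897 transcript identifiers in the guide names matched the gene table used here. The files do not pair the identifiers with gene names, and guide positions come without a chromosome, so no gene or coordinate is given. The 19 gene lists fixed for the comparison therefore matched 0 elements and were not tested.

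Guides with a mean of at least 10 over the 4 libraries were kept, 66874 in all, of which 1277 were controls. D21 was compared with D0 by limma (version 3.58.1, R 4.3.3) with trended, robust variance on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05. Elements with at least 3 guides were tested by one-sided alpha robust rank aggregation (RRA) in each direction. The ranks came from the moderated limma statistic and the top 25% of ranks entered. That statistic was taken on the deposited scale and not relative to the controls. A guide's rank therefore depends on its spread as well as on its change, and a variable guide unchanged relative to controls can rank as enriched. The null used 5000000 random draws per set size, so that 2e-07 is the smallest p the draws can give, and Benjamini-Hochberg adjustment at 0.05 was applied per direction. The p of an RRA rests on the guides of an element ranking together and takes guides as independent units. The labels call the 2 clones independent, and each clone gave 1 library per day.

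Fold changes are on the log2(value + 1) scale, which understates the change of low guides, and are given relative to the median of the control guides in the same clone. That centring was needed because the deposited scaling moved the median guide at D21 by -1.72 on the log2 scale. Errors are SDs over the guides of an element. Calculations other than limma used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

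The rule for named elements took, in each direction, those past adjusted p 0.05 with the smallest RRA p, with ties broken by the larger absolute mean guide log2 fold change. Since the identifiers have no gene names, it was stopped at 2 per direction, and the rest are described by rank. The groups, tests, named-element rule and main alternatives were fixed before the data were examined. Both days carry the same clone letters. Guides that stood higher in clone a than clone b at D0 also did so at D21 (r = 0.39 across guides), and the labels name the same clone, so clone pairs the libraries. The main fit, fixed before the data were examined, left this pairing out. The fit with the clone as a replicate block was run as an alternative.

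Other alternatives were a pseudocount of 10, no filter, a mean of at least 50, control guides set to equal medians, each library left out, other RRA settings, limma on element means, and a threshold of 0.25. The fits and the RRA were tested on simulated data built from the real guides and the spread of the controls, with 50 of the 6634 elements changed at each fold and direction. Every guide of a changed element was given the element's full change, which real guides need not show. At 4-fold, 49 of 50 enriched and 49 of 50 depleted elements were recovered. At 2-fold, 17 of 50 enriched and 10 of 50 depleted elements were recovered. Among the unchanged elements 2 were called in each direction. The simulated fit passed 17667 single guides, against 0 in the real libraries, with a median standard error of 0.753 against 0.671. The simulation thus did not match the real guide-level test, and the recovery holds only for the simulated spread and for elements whose guides all act alike.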

Results

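A CRISPR interference screen was carried out in BJ skin fibroblasts in which tamoxifen switches on oncogenic HRAS. CRISPR interference brings dCas9 to a promoter and lowers transcription there, and the share of each guide in the cells' DNA reads out how cells carrying it fared. There were 2 libraries at D0 and 2 at D21, from clones a and b, with about 19144452 to 22902359 reads each. The comparison of D21 with D0 asked which targeted elements changed the abundance of cells over 21 days of HRAS induction. Without a D21 library from untreated cells, effects of HRAS induction cannot be told apart from those of time in culture. The library covered 6634 elements and 1285 non-targeting control guides.

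The guide pool became very uneven by D21 in both clones. The 10 most abundant guides held 0.131% of the D0 library of clone a (95% Wilson interval 0.129 to 0.132) and 0.0736% of that of clone b (0.0725 to 0.0748). At D21 they held 38.7% in clone a (38.65 to 38.69) and 52.6% in clone b (52.57 to 52.61), and 8 of the 10 were the same guides. The most abundant guide was the same in both clones at D21, with 11.5% of clone a (11.45 to 11.47) and 19.8% of clone b (19.75 to 19.78). The Gini index, which is 0 when all guides are equal, was 0.314 and 0.312 at D0 in clones a and b and 0.763 and 0.834 at D21. Guide rows without reads rose from 232 to 1418 in clone a and from 136 to 2093 in clone b. With 2 libraries per day an exact test cannot go below p = 0.333 unpaired or p = 0.5 paired by clone, so the libraries are given as values.

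**Figure D1:**
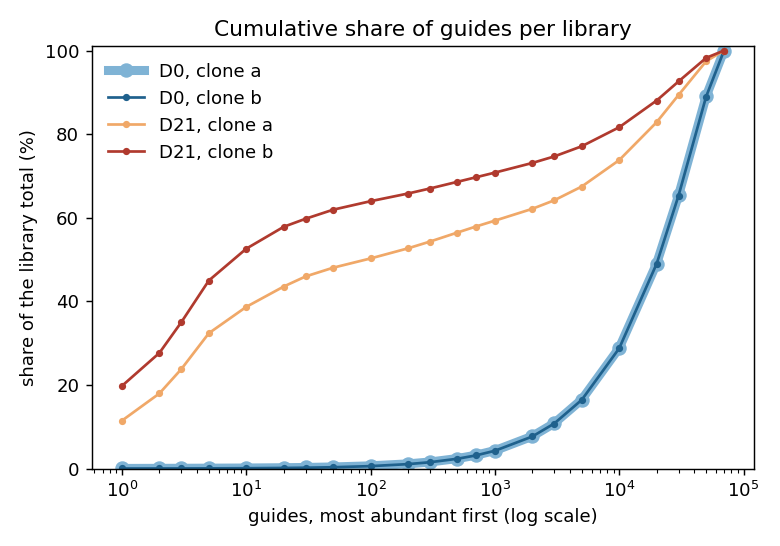
Cumulative share of the library total (y axis, %) held by guides ordered from the most abundant (x axis, log scale), with 1 line per library. The D0 lines overlap. The 10 most abundant guides reached 38.7% and 52.6% at D21 and stayed under 0.2% at D0.

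With most of the D21 total in few guides, the remaining guides had lower values at D21 under the deposited scaling. The median log2 change of control guides was -1.45 in clone a and -2.02 in clone b, and that of targeting guides was -1.47 and -1.97. All further fold changes are relative to the control median of the same clone. The element calls by RRA are not, since the limma statistic behind their ranks was taken on the deposited scale. Both clones entered those calls, so agreement of the clones in sign among called elements is no separate support. Single control guides spanned -1.99 to 2.05 in clone a and -2.48 to 2.19 in clone b over their central 95%.

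A set of 19 elements was enriched at D21 relative to D0, with all 19 above the control median in both clones. The largest mean change was that of LH13515, an element of the library's common module with an Ensembl transcript name. Its 10 guides rose by a mean log2 of 4.24 ± 2.26 (SD over guides, n = 10), 18.9-fold, with 3.88 in clone a and 4.60 in clone b. Of these guides, 8 lay above the control range in both clones. LH13888, an element of the hff_unique module with an assembled transcript name, rose by 3.71 ± 4.06 (SD over guides, n = 10), 13.1-fold, with 3.12 in clone a and 4.31 in clone b. In LH13888 the change was split, with 5 guides above the control range in both clones, 3 of them over 64-fold.

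Among the other 17 enriched elements the mean log2 change ran from 0.48 to 3.03 with a median of 1.24. The third by rank rose 8.18-fold, with 11 of its 12 guides above the control range in both clones. Of the 19 elements, 10 had no guide above the control range in both clones. They included the element of rank 5, which rose 2.73-fold. The adjusted p of LH13515 and of LH13888 was 0.000221 (RRA, Benjamini-Hochberg), from the smallest p the draws can give. By limma on element means with control guides at equal medians, taking libraries as replicates, 3 elements were enriched at an adjusted p under 0.05. LH13515 and LH13888 were among them, at 0.00139 and 0.0159 by that limma test. With the clone as a replicate block 89 were enriched, in a fit that rests almost wholly on variance pooled across elements. The count of 19 became 12 without D0 of clone b, 9 without D21 of clone a and 12 without D21 of clone b, with 12, 9 and 10 of the 19 among them, and with control guides at equal medians 25 were called, with 15 of the 19.

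A set of 26 elements was depleted at D21, all 26 below the control median in both clones. LH16749, an hff_unique element with an assembled transcript name, fell by 3.65 ± 0.88 on the log2 scale (SD over guides, n = 10), which was 12.5-fold, with -3.90 in clone a and -3.40 in clone b. All 10 of its guides lay below the control range in clone a and 7 did in clone b. Its mean signal was 124 and 198 at D0 and 1.91 and 6.12 at D21 in clones a and b, so the last values were close to the floor of 1, and with a pseudocount of 10 its log2 change was -1.87. LH00938, whose guides are listed in the common and hff_ips modules, fell by 2.64 ± 1.42 (SD over guides, n = 10), 6.22-fold, with -2.67 in clone a and -2.61 in clone b, and -1.97 with a pseudocount of 10. Of its 10 guides, 7 lay below the control range in clone a, 5 in clone b and 4 in both, and its highest guide stood at 0.40.

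The other 24 depleted elements had mean log2 changes from -2.51 to -1.03, with a median of -1.65. All 26 fell by at least 2-fold on average, and the median element had 2 guides below the control range in both clones. The adjusted p of LH16749 and of LH00938 was 0.000442 (RRA, Benjamini-Hochberg). With the clone as a replicate block 46 elements were depleted, 25 of the 26 among them, and with control guides at equal medians 60 were, again with 25 of the 26. The count was 12 without D0 of clone a, 16 without D0 of clone b, 8 without D21 of clone a and 16 without D21 of clone b, with 11, 12, 5 and 13 of the 26 among them. LH16749 had an adjusted p of 0.34 (RRA) and a log2 change of -3.12 without D21 of clone a, where only the D0 pair gives the spread, against 8.845e-05 to 0.0247 in its other tested RRA settings. By limma on element means with control guides at equal medians its adjusted p was 0.0678, and 1 element, LH00938, was depleted with an adjusted p of 0.0155. With the clone as a replicate block the same limma test gave LH16749 an adjusted p of 2.4e-18 and called 126 elements depleted, but with 1 residual degree of freedom these rest almost wholly on variance pooled across elements.

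**Figure D2:**
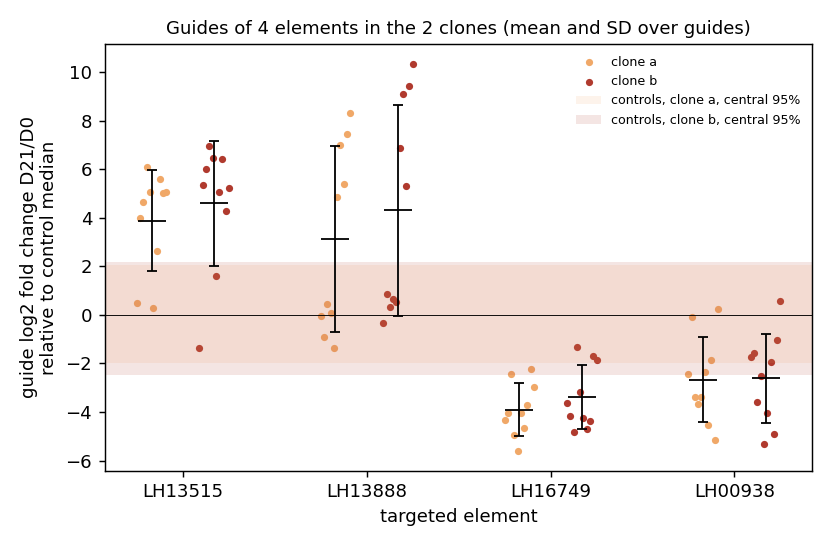
Log2 fold change of each guide from D0 to D21 relative to the control median (y axis) for the 4 named elements (x axis), with clones a and b side by side. Points are guides, black bars are the mean and SD over 10 guides, and shaded bands are the central 95% of control guides. Most LH13515 guides lie above and most LH16749 guides below the bands in both clones.

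No single guide passed the threshold by itself. Of 66874 guides, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower, while at an unadjusted p under 0.05 there were 109 higher and 35792 lower. With the clone as a replicate block limma called 77 guides higher and 39739 lower on the deposited scale, where the median guide fell by 1.72. Without D21 of clone a limma called 1058 higher and 52799 lower, and without D21 of clone b 1151 higher and 39391 lower. In these fits the spread comes from the D0 pair and the lone D21 library is assumed to vary like it, so the counts are not comparable with those of all 4 libraries. With control guides at equal medians limma called 0 in either direction, and 1356 were higher and 1494 lower at an unadjusted p under 0.05, where 3343.7 in all would be by chance. Adding the clone as a replicate block, an alternative chosen after seeing the data, again gave 0 calls by limma, with 2326 higher and 2477 lower at an unadjusted p under 0.05.

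The changes in clone a and clone b were correlated. Across 6634 elements the log2 changes of the clones had a Pearson r of 0.39 and a Spearman rho of 0.22. Across the 6589 elements that were not called, r was 0.30 and rho 0.21. Across 66874 guides r was 0.22 and rho 0.13, and across the 1277 control guides r was 0.073. Guides and elements are not independent replicates, so no p is given. Of the 66 elements with the highest change in each clone, 19 were shared where 0.657 would be by chance, and of the 66 with the lowest, 37 were shared with the same 0.657 by chance. A single guide can set the mean of an element, so a shared element need not reflect most of its guides.

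For the 4 named elements, no difference between the clones passed the test. The difference of clone b minus clone a was 0.71 for LH13515, 1.19 for LH13888, 0.51 for LH16749 and 0.06 for LH00938. Two-sided exact sign-flip tests over guides gave p = 0.104, 0.0156, 0.357 and 0.939, or 0.207, 0.0625, 0.477 and 0.939 after Benjamini-Hochberg adjustment over the 4. These tests compare the libraries, since each clone has 1 library per day. The clone b value was above the clone a value in 14 of the 19 enriched and 19 of the 26 depleted elements, a difference that was not tested, and the median over all 6634 elements was -0.04 in clone a and 0.02 in clone b.

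Control guides grouped at random into 127 sets of 10 gave few low p-values. Over 20 regroupings, a mean of 3.35 sets reached an unadjusted RRA p under 0.05 for enrichment and 3.05 for depletion, against 6.35 by chance. Among the real elements 392 did so for enrichment and 414 for depletion, against 331.7 by chance. Random groups of controls cannot show dependence among the guides of an element, so they do not test the element calls for it. The controls also spread less than the targeting guides they were ranked with, which may lower their count. Their SDs of log2 change were 0.989 against 1.16 in clone a and 1.10 against 1.26 in clone b.

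**Figure D3:**
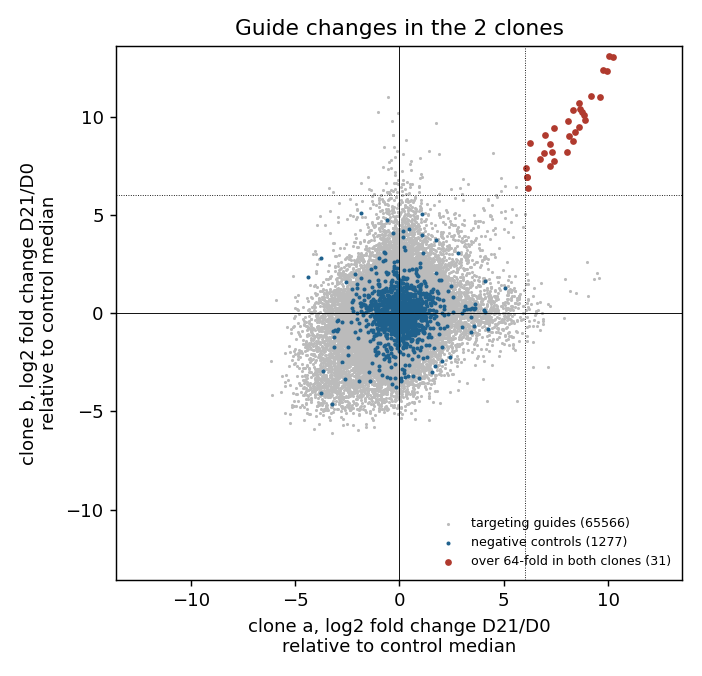
Log2 fold change of each guide from D0 to D21 relative to the control median, clone a (x axis) against clone b (y axis). Grey points are targeting guides, blue points the 1277 control guides, and red points the 31 guides above 64-fold in both clones (dotted lines).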

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

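The 4 named elements kept their direction in all 48 alternative values. Of these, 36 had an RRA test, and LH16749 lost its call in 1 of them, without D21 of clone a, at a log2 change of -3.12. A day left with 1 library is assumed to vary like the other day, whose pair alone gives the spread. By limma on control-centred element means LH16749 passed the threshold only with the replicate block. Alternatives with control guides at equal medians and a replicate block, on control-centred element means, or with every table row kept were chosen after seeing the data. For the counts that moved by over 1.5 times, the cause was not tested unless said. Leaving out each library gave 9 to 17 enriched and 8 to 16 depleted elements, and 0 to 1151 guides higher and 0 to 52799 lower. The clone as a replicate block gave 77 guides higher, 39739 lower and 46 elements depleted, and changed no RRA call of a named element. A threshold of 0.25 gave 249 guides higher, 56841 lower, 39 elements enriched and 53 depleted, by construction. Enriched elements numbered 11 with the top 5% of ranks and 10 without each element's most extreme guide. Depleted elements numbered 16 with a mean of at least 50, 16 without the most extreme guide, 60 with control guides at equal medians, 70 with those and the replicate block, and 69 when guides were ranked by mean log2 fold change. By limma on element means, 4 were enriched and 6597 depleted, or 4 and 6599 with the replicate block, since the deposited scaling moved the bulk down. Centred on controls, limma on element means gave 3 enriched and 1 depleted, or 89 and 126 with the replicate block. The correlation of the clones was 0.178 (pseudocount 10) and 0.205 (mean of at least 50) across guides and 0.315 across elements (pseudocount 10). Restricted to guides with a mean of at least 10, the Gini index at D0 was 0.307 and 0.305. Rescaling to equal totals was not run because the totals are equal, and the planned count model was not run. The fixed gene lists gave no value under any setting. At D21 the median control guide had only 99 and 67 reads in clones a and b, which limits the depletion that can be seen.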

Other observations

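The tests in this part were chosen after the data were seen. Most guide names carry an Ensembl transcript, an assembled transcript or in their place a tag P1, P2 or P1P2, which the sources used here do not explain, and 29 elements have another kind of name. Of the 1351 elements with that tag, 14 were depleted (1.04%), against 12 of the other 5283 (0.227%). Fisher's exact test gave p = 0.00016, or 0.0032 after Benjamini-Hochberg adjustment over 20 tests of element classes. Among enriched elements the tag was found in 8 of 1351 against 11 of 5283, which did not pass the adjustment (adjusted p = 0.194 by Fisher's exact test). The excess among depleted elements had a Fisher's exact p of 0.0596 without D21 of clone a, where 4 of 8 depleted elements carried the tag. The 3 library modules held enriched and depleted elements in shares that did not pass the adjustment.

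Guides that fell by more than 8-fold relative to controls numbered 1088 in clone a and 1354 in clone b, with 312 in both, against 51.0 by chance within 10 bins of D0 abundance. There were 2 control guides among the 312. Guides that rose by more than 8-fold numbered 852 and 1109, with 108 in both against 14.3 by chance, and 0 of the 108 were controls. Controls were 1277 of the 66874 guides, so few would be in either set by chance. Within clone a, 1.33% of controls and 1.27% of targeting guides rose by more than 8-fold, and 0.705% and 1.64% fell by as much. In clone b the shares were 1.17% and 1.67% for rises and 1.49% and 2.04% for falls.

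A small set of guides expanded in both clones. A total of 31 guides rose by more than 64-fold in both, and together they made up 42.5% of D21 in clone a and 56.9% in clone b, from 0.186% and 0.091% at D0. Independent chance expansion would give an overlap of 0.201 guides within 10 bins of D0 abundance, and carry-over of reads or cells between the D21 samples is argued against because the smaller D21 value of each of the 31 was at least 31.7% of the larger, whereas the guides above a signal of 50000 allow a carry-over rate of at most 0.167% from clone a and 0.0743% from clone b. Knockdown of the element by most of its guides is argued against for the set, since the other guides of the 31 elements had a median log2 change of 0.072 (SD between elements 0.904) and that median lay within the control range in 30 of them, with LH13515 the exception at 4.67. LH13888 was among the 30 at 0.37, but 3 of its guides were in the expanding set and 2 of its other 7 lay above controls. An effect of single guides, on the element or elsewhere, may remain, as may cells shared by the cultures before they expanded, and neither was tested since guide sequences were not analysed here and D0 is the earliest sample.

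The guides that dominated D21 were also abundant at D0. The most abundant D21 guide ranked 1 at D0 in both clones, with a signal of 5256 in clone a and 1895 in clone b. A single rate of carry-over from the clone a D21 library into both D0 libraries is argued against, since clone b allows at most 0.107% and clone a needs at least 0.217%. A higher starting share alone is argued against too, since the median log2 ratio of clone a to clone b at D0 was 0.88 for the 18 shared dominant guides, beyond 10000 random sets matched on D0 (permutation p = 0.0001, the smallest they can give). Expansion before the D0 sample was taken, or carry-over into D0 of the same clone, may explain the rest. Both predict a D0 signal higher in the clone where a guide dominates, and an exact two-sided permutation test of 7 guides dominant in clone a against 4 in clone b gave p = 0.0909, which leaves that joint prediction open and does not separate them. The 18 shared dominant guides were not in that test. For the most abundant of them the D0 signal was higher in clone a, while its D21 share was higher in clone b, at 19.8% against 11.5%. The median D0 signal of the 18 was 1091 in clone a and 742 in clone b. The 31 expanding guides together held 0.186% and 0.091% of D0, and 42.5% and 56.9% of D21, in clones a and b. A higher D0 signal in clone a with a larger D21 share in clone b runs against that prediction, but was not tested.

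Some called elements lay side by side. By identifier order and guide position, 3 pairs of called elements lay within 10 kb of each other, 1 pair enriched and 2 depleted, and 0 pairs of opposite direction. Their distances ran from 492.5 to 1248.5 bp, so the 2 elements of a pair may not be separate loci. Random sets of the same sizes held 0.0388 pairs on average (permutation p = 0.0001, the smallest 10000 sets can give), so chance placement of called elements is argued against. Guides counted in both elements of a pair are argued against too, as the pairs shared 0 guides. A shared local effect on neighbouring elements is a candidate explanation that was not tested further, and the files give positions without a chromosome.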
